A study of Mus musculus with 10 samples.

How the data were processed

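The study measured nascent RNA in mouse embryonic stem cells kept in medium with LIF and the inhibitors PD0325901 (1 µM) and CHIR99021 (3 µM). Per the labels, cells were given 2 mM bromouridine for 10 min, and RNA that had taken it up was purified with an antibody, freed of ribosomal RNA and sequenced. The growth protocol speaks of culture on irradiated or mitomycin-treated fibroblasts that were depleted before use, and the extraction protocol of feeder-free dishes. The authors deposited 1 table of intronic RPKM (reads in introns scaled by intron length and library depth) for 24901 genes in 8 columns, 6 of them single libraries and 2 named averages of the CJ7_WT and Eed_null replicates. BWA and the mouse build mm9 are given as the alignment, the version of BWA is not given, and the counter, gene annotation, strand handling and the reads taken as the depth are not given in the sources used here.

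The unit was tested on the values. RPKM of 1 gene are whole multiples of a step set by its length and the depth of the library, and whole reads (within 0.01 of a read, up to 0.06 for high values) could be recovered for 20813 of the 20817 genes with 6 or more columns above 0 (99.98%). When the values of 300 genes were jittered by 0.5%, 5 gave whole reads as small as the real ones. Both average columns also gave whole reads on 1 step, so they behave as pooled reads and not as means of replicates. Recovered intronic reads came to between 26622745 and 39307079 in the 6 libraries, 87474586 in pooled CJ7_WT and 72878664 in pooled Eed_null. Of the 24901 genes, 962 were at 0 in every column, 160 had the same 8 values as another gene, which points to shared introns, and 115 symbols stood on more than 1 line.

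Groups follow the sample titles. The label fields conflict with them in that the Eed null samples carry the genotype EloA null and the line CCE28, while their column names read CJ7. EloA_WT also carries CCE28 and the mutants CJ7. The titles and column names were used.

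For the 6 libraries, log2 of RPKM plus 0.1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend) in 1 fit of 3 groups, over 15161 genes with a mean of at least 0.1 RPKM. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, 3 residual and 2.76 prior degrees of freedom. The median standard deviation of a gene between replicates was 0.195 on the log2 scale. The comparisons were EloA_K754M and EloA_K754R against EloA_WT, the mean of both against EloA_WT, and EloA_K754M against EloA_K754R. Replicate numbers were not used as a block, because nothing in the labels says that they mark a shared day. In this text "rose", "fell" and "called" mean an adjusted p under the threshold, and ± is the standard deviation of n = 2 libraries.

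The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 25 lists were PRC2-bound developmental transcription factors, Hox clusters, PRC2-bound signalling genes, naive and primed pluripotency, neuroectoderm, mesoderm, endoderm, trophectoderm, embryonic fibroblast (feeder) markers, PRC1 and PRC2 subunits, Elongin and elongation factors, p53 targets, the integrated stress and unfolded protein response, heat shock, immediate early genes, 2-cell and germline genes, imprinted genes, cell cycle, ribosomal proteins, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, interferon genes and very long genes. They were written from general knowledge and some share members, such as Atf3 and Sesn2. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. That second form has only the 3 residual degrees of freedom, so a call lost there need not mean that the genes are correlated. Fry was also used, which asks whether a list's genes move one way on balance and compares them with no other genes. A list's median is over its tested genes.

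Named genes were, for each mutant against EloA_WT, the 10 largest rises and 10 largest falls past the threshold with both mutant values beyond both wild-type values and at least 0.5 RPKM in the higher group. Where fewer passed, those with the smallest unadjusted p were added as values only. Between the mutants the rule took the 3 largest each way, and for Eed_null the 10 largest ratios each way. Further named were up to 4 members with the largest change of each list called or holding a called gene, and in each comparison Tceb3, Eed, Ezh2, Suz12, Pou5f1, Nanog and Klf4. Unnamed gene models were passed over.

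Eed_null was compared with CJ7_WT as the log2 ratio of RPKM plus 0.1 over 14890 genes, without a test. The median of each list was placed among 10000 random lists of the same size drawn from 20 level bins. Fold ranges are exact 95% intervals for a ratio of read counts (scipy 1.17.1). They cover counting error only, and reads without molecular identifiers are not independent molecules. Against 0 reads the fold is a lower bound computed with 3 reads in the pooled column, and no fold is given when both columns hold 3 reads or fewer. Genes were assigned to chromosomes by identifier from GENCODE release M 21, which matched 22887 of the table's genes and not the other 2014. No coordinates are given, since that annotation is on another build than mm9.

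The change by level was the median over quartiles of pooled CJ7_WT RPKM. Relations across genes were Pearson and Spearman correlations, with 100 simulated sets of unchanged groups that share the EloA_WT libraries for the relation of both mutants. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The fit was tested on simulated data with changes planted among 15113 tested genes. Of planted log2 changes of 2 it recovered 96.3% in EloA_K754M, 89.5% in EloA_K754R and 92.55% between the mutants. For the mean of both mutants it called 72.0% of 189 planted genes. That share is not a recovery of mean changes of 2, because only 95 genes were changed in EloA_K754R. Genes changed in EloA_K754M alone have a mean change below 2. In the 4 comparisons the sign was right in 100%, with 19 to 32 false calls per comparison.

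Alternatives were an offset of 0.01 or 1, no filter or a mean of at least 0.5 RPKM, equal library medians, quantile normalization, no variance trend, only the 2 groups compared, a replicate block, and leaving out each library. In the last case the lone sample of a group is assumed to vary like the other groups. Chosen after seeing the data were voom on recovered reads, a minimum mean of 50 recovered reads, equal medians per chromosome and leaving out chromosome 11. So were removal of a trend on counted intron length and subtraction of the median of olfactory and vomeronasal receptor genes. Coverage tracks of the series were not used here.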

Results

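Newly made RNA was profiled in mouse embryonic stem cells by Bru-seq, in which bromouridine is taken up into RNA during a short labelling time and the labelled RNA is captured with an antibody. The values are intronic RPKM, the reads in a gene's introns scaled by intron length and by the reads of the library, which follow ongoing transcription more closely than stored mRNA does. The 10 samples fall into 5 groups of 2. EloA_WT, EloA_K754M and EloA_K754R carry wild-type Elongin A, a subunit of an RNA polymerase II elongation factor, or a form whose lysine K754 is replaced by methionine or arginine. CJ7_WT is a wild-type stem cell line and Eed_null has lost Eed, a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3. Each of the 6 Elongin A libraries has its own column, while CJ7_WT and Eed_null are present only as 1 pooled column each. Intronic reads came to 34650955 and 29337131 in EloA_WT, 26622745 and 27225650 in EloA_K754M, 29405166 and 39307079 in EloA_K754R, 87474586 in pooled CJ7_WT and 72878664 in pooled Eed_null.

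The label field for the parental line reads CCE28 for EloA_WT and for Eed_null, and CJ7 for the other groups, whereas the growth protocol names CJ7 for every sample. If the field is right, the substitution and the parental line differ together in both comparisons with EloA_WT, and so do the loss of Eed and the line between Eed_null and CJ7_WT. The p-values measure only the spread between these samples, which are not said to be separate cultures and may differ by technical steps alone.

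The comparison of EloA_K754M with EloA_WT asks which genes are transcribed differently when the lysine is replaced by methionine. Elongin A itself (Tceb3, ENSMUSG00000028668) stood at 1.46 and 1.98 RPKM in the EloA_K754M libraries and 1.83 and 2.03 in EloA_WT (log2 change −0.17, adjusted p = 0.704). Eed stood at 14.3 and 17.1 against 10.6 and 14.9 RPKM (0.31, adjusted p = 0.562). Intronic reads do not check a point substitution. Chac1, Phgdh, Slc1a4, Pck2 and Gpt2 were among the largest falls. Chac1, a glutathione-degrading enzyme induced by stress, went from 2.34 ± 0.463 RPKM in EloA_WT to 0.266 ± 0.0671 in EloA_K754M (SD, n = 2 each; log2 change −2.74, SE 0.22, adjusted p = 0.0264). Phgdh, the first enzyme of serine synthesis, went from 2.55 ± 0.180 to 0.408 ± 0.0850 RPKM (−2.39, adjusted p = 0.0281). Slc1a4, a neutral amino acid transporter, fell by 2.54 on the log2 scale to 0.419 ± 0.0661 RPKM, Pck2, a mitochondrial gluconeogenic enzyme, by 2.21 to 0.600 ± 0.0343, and Gpt2, an alanine transaminase, by 2.17 to 1.20 ± 0.250. Their adjusted p were 0.0176, 0.0264 and 0.0402.

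Other named genes that fell were Sncg, encoding gamma-synuclein (6.38 ± 0.945 to 0.868 ± 0.0495 RPKM, log2 change −2.74), the Y-linked Eif2s3y (3.71 ± 0.735 to 0.465 ± 0.0617, −2.74), Aspa, which cleaves N-acetylaspartate (5.89 ± 0.323 to 0.944 ± 0.150, −2.53), Cyb5r2 (0.967 ± 0.106 to 0.0984 ± 0.00172, −2.42) and the surface antigen gene Ly6a (3.66 ± 0.600 to 0.726 ± 0.0127, −2.18). Their adjusted p lay between 0.0115 for Sncg and 0.0402 for Aspa. Slc1a4 and Aspa lie on chromosome 11, whose genes were lower as a whole. The pooled CJ7_WT value lay beyond both EloA_WT values on the same side for 29 of the 31 genes that fell, against 53.1% of all tested genes on that side. These genes were called on the same EloA_WT values, which by itself favours this outcome, so the comparison does not show which group differs. In all, limma called 33 of 15161 genes, 2 higher and 31 lower, with 2334 at an unadjusted p under 0.05. The 2 that rose are the unnamed gene models Gm7325 (2.63 to 6.91 RPKM, adjusted p = 0.0482) and Gm9901 (0 in both EloA_WT libraries, 15.1 and 7.36 RPKM in EloA_K754M, adjusted p = 0.0115), chosen after their values were seen. The reads behind Gm9901 are not given here. An RPKM of this size can rest on very few reads, as for Olfr837, at 9.98 RPKM on 2 reads in pooled Eed_null.

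In this fit, which has no replicate block, no named gene passed the threshold upward, and the 10 closest are given as values only. A replicate block changes this, and stands among the alternatives because nothing in the labels establishes the pairing. Folr2, a folate receptor, stood at 0.714 ± 0.0653 against 0.146 ± 0.0174 RPKM (log2 change 1.73, adjusted p = 0.0510), and Dok1, an adaptor of tyrosine kinases, at 4.80 ± 1.18 against 1.53 ± 0.311 (1.58, adjusted p = 0.0762). The log2 changes of Dgki, Rab19, AC139849.1, Insl3, Wdr35, Basp1, Pid1 and Lpp lay between 0.89 and 1.41, with adjusted p from 0.0632 to 0.0810. Of the genes fixed beforehand, Ezh2 and Suz12, the catalytic and a structural subunit of PRC2, stood at 5.07 ± 0.576 against 5.28 ± 0.181 RPKM and 8.75 ± 0.622 against 13.9 ± 1.99 (log2 changes −0.06, which turns positive with equal library medians and with quantile normalization, and −0.65; adjusted p = 0.875 and 0.141). The pluripotency factors Pou5f1, Nanog and Klf4 had log2 changes of 0.33, −0.26 and 0.20, with adjusted p of 0.684, 0.479 and 0.723.

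The integrated stress and unfolded protein response, which includes serine synthesis genes driven by Atf4, was the list with the smallest camera p. Of its 25 measured genes 4 fell (Chac1, Phgdh, Psat1 and Mthfd2) and 18 did when adjusted over the list alone, 22 had negative changes, and the median log2 change was −0.93 (adjusted p = 9.7e-13, and adjusted p = 0.0875 with an estimated correlation). Trib3, a pseudokinase induced by Atf4, stood at 0.364 ± 0.215 against 3.06 ± 0.578 RPKM, Nupr1 at 0.332 ± 0.103 against 2.78 ± 0.154, and the cystine transporter gene Slc7a11 at 0.0735 ± 0.0697 against 0.809 ± 0.155. The adjusted p of these 3 were 0.0810, 0.104 and 0.0868. By library the list median was −0.86 and −1.02 in EloA_K754M and −1.01 in the pooled CJ7_WT column, each against EloA_WT. These medians are not matched for intron length. Relative to genes of like length and level, the list in CJ7_WT lay at −0.406 against EloA_WT. Only 1 of the list's genes lies on chromosome 11.

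**Figure D1:**
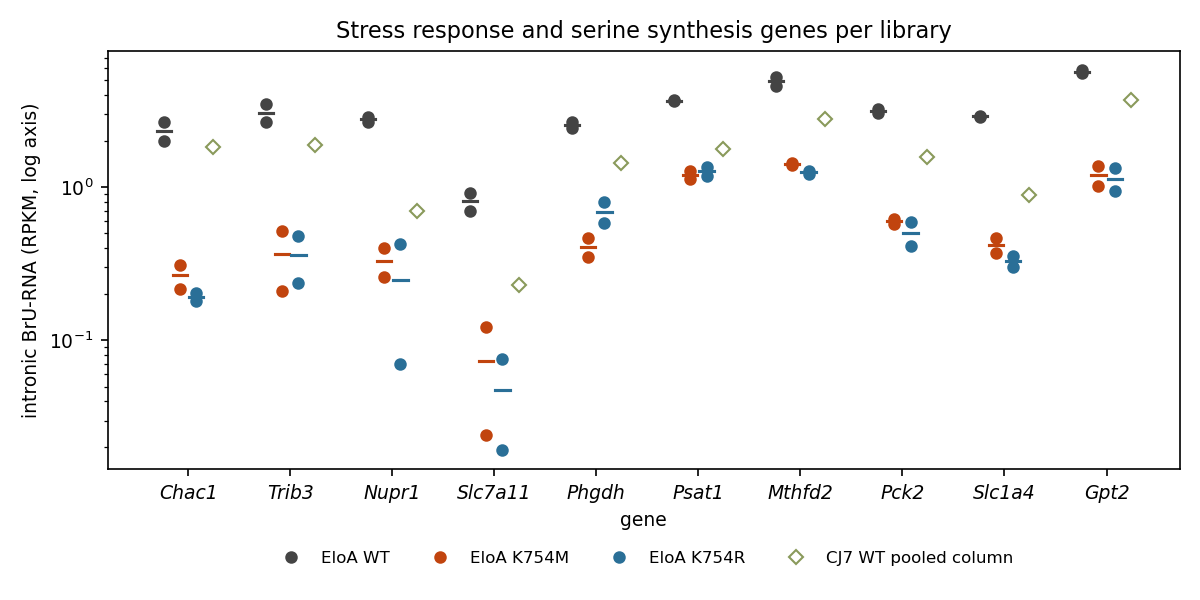
Intronic RPKM (vertical axis, log scale) of 7 genes of the stress response list and of Pck2, Slc1a4 and Gpt2, with dots for single libraries, bars for group means and open diamonds for the pooled CJ7_WT column. Chac1 is at a mean of 2.34 RPKM in EloA_WT and at 0.266 and 0.193 in EloA_K754M and EloA_K754R. CJ7_WT lies between EloA_WT and the mutants for each of the 10 genes, all of which fell in a mutant. Over the whole list the raw median of CJ7_WT was as low as that of EloA_K754M, at −1.01 against −0.86 and −1.02. Against CJ7_WT the EloA_K754M libraries lay at −0.521 and −0.365 relative to genes of like length and level. Relative to all genes they lay at −0.124 and −0.021. Both measures were chosen after the data were seen.

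Embryonic fibroblast markers, included because feeder cells could remain in the cultures, had positive changes for each of the 28 measured genes (median 0.42; adjusted p = 3.78e-09, and adjusted p = 0.413 with an estimated correlation). None was called by limma over all genes, 4 were when adjusted over the list alone, 9 had an unadjusted p under 0.05 and voom called 3. The matrix genes Ccdc80, Tnc, Lox and Col5a2 had log2 changes of 0.82, 0.74, 0.72 and 0.71, and the abundant Fn1 stood at 9.02 and 9.38 RPKM in EloA_K754M against 8.48 and 9.11. The list median was 0.62 and 0.24 in the 2 EloA_K754M libraries and 0.39 in pooled CJ7_WT.

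Camera called 7 further lists, none with a gene called by limma over all genes, and each lost its call with an estimated correlation. Hox cluster genes, which set body position, had 18 of 22 positive changes (median 0.37; adjusted p = 0.00934, 0.552 with an estimated correlation), 2 at an unadjusted p under 0.05, and 0 when adjusted over the list alone or called by voom. Hoxc10 rested on 16 against 3 reads and Hoxa2 on 11 against 7, and Hoxc9 and Hoxd8 had changes of 0.80 and 0.70. The Hox call ended without EloA_WT replicate 2 (adjusted p = 0.105) or EloA_K754M replicate 1 (0.249), and with quantile normalization (0.267). Immediate early and MAPK feedback genes had 17 of 20 positive (median 0.32; 0.00737, 0.368 with an estimated correlation), among them Spry4 at 1.5, Etv4 at 1.19, Phlda1 at 0.66 and Atf3 at −0.93. Imprinted genes had 16 of 25 positive (median 0.19; 0.00934, 0.344 with an estimated correlation), with Rtl1 at 0.99, Sgce at 0.93, Grb10 at −1.66 and Phlda2 at 0 against 3 reads. Both calls ended without EloA_WT replicate 1 (0.0936 and 0.0562) or EloA_K754M replicate 1 (0.0904 and 0.130). At an unadjusted p under 0.05 the immediate early list held 5 genes and the imprinted list 7, voom called 0 and 4, and adjusted over the list alone 1 and 4 passed.

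Heat shock and oxidative stress genes had 21 of 25 negative changes (median −0.24; adjusted p = 0.00934, 0.344 with an estimated correlation), with Sqstm1 at −1.01, Hmox1 at −0.58 and Gsr at −0.53. Cell cycle genes had 34 of 42 negative (median −0.17; 0.0204, 0.413 with an estimated correlation), with Top2a at −0.90, Cdc6 at −0.77, Ccnd1 at −0.60 and Mcm10 at −0.45. Ribosomal protein genes had 27 of 36 negative (median −0.26; 0.0353, 0.606 with an estimated correlation), with Rpl27 at −1.04, Rpl23 at −0.67, Rps27a at −0.59 and Rplp0 at −0.57, the first 3 of them on chromosome 11. Endoderm genes had 10 of 12 positive (median 0.39; 0.0198, 0.413 with an estimated correlation), with Ttr at 0.94, Amn at 0.84, Cxcr4 at 0.74 and Hnf4a at 0.60. In these 4 lists, 7, 5, 4 and 3 genes had an unadjusted p under 0.05, voom called 1, 1, 2 and 0, and 1, 2, 0 and 0 passed when adjusted over the list alone. Without EloA_WT replicate 2 the heat shock (0.0909), cell cycle (0.299) and ribosomal calls (0.105) ended. Without EloA_K754M replicate 2 the cell cycle (0.102), ribosomal (0.261) and endoderm calls (0.0915) ended, and without EloA_WT replicate 1 the ribosomal (0.0879) and endoderm calls (0.0936) did. The ribosomal call also ended without EloA_K754R replicate 1 (0.0572) or 2 (0.0561). Other settings ended calls as well. The cell cycle, ribosomal and endoderm calls ended with quantile normalization (0.203, 0.194 and 0.0704), with the length trend removed (0.159, 0.156 and 0.0668), from a mean of 0.5 RPKM (0.0949, 0.164 and 0.477) and from 50 reads (0.0620, 0.0633 and 0.0633). The cell cycle call also ended with equal medians (0.143) and the endoderm call without a filter (0.0712).

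The other 16 lists were not called. Their adjusted p were 0.126 for developmental transcription factors bound by PRC2, 0.983 for PRC2-bound signalling genes, 0.0554 for naive pluripotency, 0.431 for primed pluripotency, 0.886 for neuroectoderm, 0.202 for mesoderm, 0.245 for trophectoderm, 0.886 for PRC1 and PRC2 subunits, 0.838 for Elongin and elongation factors, 0.232 for p53 targets, 0.943 for 2-cell and germline genes, 0.576 for glycolysis, 0.262 for cholesterol synthesis, 0.469 for oxidative phosphorylation, 0.660 for interferon genes and 0.0511 for very long genes. The 33 single-gene calls became 2 without EloA_WT replicate 1, 11 without EloA_WT replicate 2, 52 without EloA_K754M replicate 1, 11 without EloA_K754M replicate 2 and 3 without either EloA_K754R replicate. Their balance was not stable, with 43 higher and 9 lower without EloA_K754M replicate 1 and 9 higher and 2 lower without replicate 2, and voom called 104 higher and 239 lower. The median change of all genes was −0.06, and 0.07 with equal library medians, where 16 genes were called.

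The comparison of EloA_K754R with EloA_WT asks the same for arginine, which keeps a positive charge at that position. Tceb3 stood at 1.12 and 1.30 RPKM in EloA_K754R against 1.83 and 2.03 in EloA_WT (log2 change −0.63, adjusted p = 0.104), and Eed at 10.3 and 12.7 against 10.6 and 14.9 (−0.14, which turns positive with equal library medians and with quantile normalization; adjusted p = 0.731). Again the stress genes Nupr1, Chac1, Trib3 and Slc7a11 were among the largest falls. Nupr1 went from 2.78 ± 0.154 to 0.247 ± 0.250 RPKM (SD, n = 2 each; 9.63-fold lower, adjusted p = 0.0421), Chac1 from 2.34 ± 0.463 to 0.193 ± 0.0151 (8.28-fold, adjusted p = 0.0127), Trib3 from 3.06 ± 0.578 to 0.359 ± 0.173 (7.10-fold, adjusted p = 0.0369), and Slc7a11 from 0.809 ± 0.155 to 0.0477 ± 0.0402 (log2 change −2.64, adjusted p = 0.0364). Slc1a4 fell to 0.328 ± 0.0380 RPKM (7.05-fold, adjusted p = 0.00931). Folds are of RPKM with the offset of 0.1 added.

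The other named genes that fell were Aspa (to 0.576 ± 0.212 RPKM), Stc2, encoding stanniocalcin (4.50 ± 1.66 to 0.541 ± 0.396), Cby3 (1.44 ± 0.383 to 0.135 ± 0.0608), P2rx3, an ATP-gated channel (1.14 ± 0.0264 to 0.120 ± 0.00527), and Sh3bgrl3, which rested on 2 reads against 28. Their adjusted p lay between 0.0120 for P2rx3 and 0.0421 for Stc2. Slc1a4, Aspa, Stc2 and Cby3 lie on chromosome 11. Of the 10 named genes that rose, 7 lie on the X chromosome. These are Pramel3 (0.0805 ± 0.00363 to 1.13 ± 0.148 RPKM, 6.81-fold, adjusted p = 0.0234), Usp26 (0.528 ± 0.160 to 2.61 ± 0.433, 4.35-fold, adjusted p = 0.0247), Scml2, a Polycomb-like protein of germ cells (0.696 ± 0.276 to 3.22 ± 0.0435, 4.30-fold, adjusted p = 0.0319), Xlr (4.06-fold), Magea10, Rragb and Magea8 (log2 changes 1.76, 1.69 and 1.60). The other 3 were Asz1, needed for piRNA production in germ cells (0.0941 ± 0.000437 to 0.889 ± 0.168 RPKM, 5.06-fold), Sohlh2, a germline transcription factor (0.608 ± 0.229 to 2.17 ± 0.105), and Rassf10, with 5 reads against 0. Their adjusted p ran from 0.0127 for Rassf10 to 0.0428 for Magea8.

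In all, 527 genes were called, 104 higher and 423 lower, and 3807 had an unadjusted p under 0.05. Of the 423 that fell, 152 (35.9%) lie on chromosome 11, which holds 8.67% of tested genes, and of the 104 that rose 32 lie on the X chromosome. Pooled CJ7_WT lay beyond both EloA_WT values on the same side for 383 of the 423 and for 79 of the 104 (53.1% and 28.8% of all tested genes). Here too the calls rest on the same EloA_WT values, which favours this outcome, so the shares of all genes are no fair measure beside it. Leaving out chromosome 11 left 204 calls, 48 higher and 156 lower. The median change of all genes was −0.14, and 0.05 with equal library medians, where 164 genes were higher and 160 lower. Without either EloA_K754M replicate it stayed at −0.14, since those libraries enter this comparison only through the spread. Each fit without 1 library has 2 residual degrees of freedom in place of 3, which by itself lowers the number of calls. Without 1 library the count fell to 6 or 9 (EloA_WT replicate 1 or 2), 1 (either EloA_K754M replicate), 3 or 8 (EloA_K754R replicate 1 or 2), and the 3 were all higher. Ezh2, Suz12, Pou5f1, Nanog and Klf4 had log2 changes of −0.01, −0.20, −0.33, 0.07 and 0.44 (adjusted p = 0.977, 0.460, 0.559, 0.823 and 0.277), and the sign of Ezh2 turned with equal medians and with quantile normalization, and those of Suz12 and Pou5f1 with the latter.

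Among the lists, 16 of the 25 stress response genes fell, 20 did when adjusted over the list alone, and 23 had negative changes (median −1.12; adjusted p = 4.84e-11, and adjusted p = 0.108 with an estimated correlation). By library the median was −1.02 and −1.21. Each of the 36 ribosomal protein genes had a negative change, 5 fell and 12 did when adjusted over the list alone (median −0.64; adjusted p = 1.16e-07, and adjusted p = 0.460 with an estimated correlation). Rpl27 went from 35.7 ± 5.25 to 14.2 ± 0.445 RPKM (−1.31, adjusted p = 0.0402) and Rpl23 from 38.2 ± 0.626 to 19.5 ± 1.16 (−0.97, adjusted p = 0.0387), while Rps27a and Rplp1 had changes of −0.93 and −0.88 that were not called. Of the ribosomal list 3 genes lie on chromosome 11, and the list median in pooled CJ7_WT was −1.50. The list median in EloA_K754R shrank to −0.29 with the length trend removed and to −0.20 with quantile normalization, still called (0.000279 and 0.00577). Fibroblast markers had 27 of 28 positive changes (median 0.38; adjusted p = 8.95e-10, and adjusted p = 0.460 with an estimated correlation). Of them only the matrix gene Tnc rose (0.82, adjusted p = 0.0438), 5 did when adjusted over the list alone, Ccdc80, Col1a2 and Col5a2 had changes of 0.77, 0.73 and 0.69, and Fn1 stood at 11.2 and 11.6 RPKM against 8.48 and 9.11. The list median was 0.55 and 0.23 by library.

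Hox genes had 17 of 22 positive changes (median 0.25; adjusted p = 0.000302, and adjusted p = 0.460 with an estimated correlation). Hoxc9 (0.0711 ± 0.0170 to 0.353 ± 0.0607 RPKM, adjusted p = 0.0453) and Hoxc10 (3 to 35 reads, adjusted p = 0.0473) rose, also when adjusted over the list alone, and Hoxa11 and Hoxc11 had changes of 1.41, on 12 against 1 read, and 1.17, neither called. Primed pluripotency genes had 11 of 15 positive (median 0.33; 0.00429, and adjusted p = 0.460 with an estimated correlation), 6 with an unadjusted p under 0.05, 0 called by limma over all genes or over the list alone, and 1 by voom. Spry4, Lefty1, Lefty2 and Dusp6 had changes of 1.56, 1.52, 1.33 and −0.81. That call ended without EloA_WT replicate 1 (0.0507). Very long genes had 12 of 19 positive (median 0.18; 0.00445, and adjusted p = 0.460 with an estimated correlation). Nbea rose from 0.172 ± 0.00100 to 0.490 ± 0.0105 RPKM (adjusted p = 0.0421, 1 gene also over the list alone), and Auts2, Dab1 and Immp2l had changes of 0.76, 0.70 and −0.56. With the trend on gene length removed the median of this list was 0.01 and its adjusted p 0.905, and the call also ended from a mean of 0.5 RPKM (0.158).

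Single members of uncalled lists passed the threshold. Polr2a, the large subunit of RNA polymerase II (10.7 ± 0.95 to 4.67 ± 0.387 RPKM, adjusted p = 0.0351), and Tceb2, which encodes Elongin B (3.75 ± 0.736 to 1.59 ± 0.139, adjusted p = 0.0475), fell, and Supt4h1 and Mllt3 of the same list had changes of −0.74 and 0.97. Polr2a and Supt4h1 lie on chromosome 11, as does Top2a, which fell by 0.74. Also past the threshold were Slit2 (1.11), Slc25a31 (1.53), Dnajb1 (−1.06), Atf3 (−1.01), Mest (−0.81), Tubb3 (−0.94), Sesn2 (−1.31) and Tfap2a (−1.07), with adjusted p from 0.0244 to 0.0475. Beside them in their lists, and not called, stood Ntrk3 (0.72), Wnt5a (0.48) and Bmp7 (0.31), Taf7l (1.14) and Dazl (−1.0), Hmox1 (−1.12) and Nqo1 (−0.85), Fos (−1.05) and Dusp1 (0.84), H19 (8 against 29 reads), Grb10 (−1.66) and Ddc (−1.02), Ncam1 (0.60), Stmn2 (−0.49) and Neurod1 (0.35), Ddit4 (−1.12), Pmaip1 (0.87) and Ccng1 (−0.75), Krt8 (−0.99), Krt18 (−0.86) and Gata3 (−0.76), and Aurkb (−0.83), Pcna (−0.59) and Ccnd2 (0.45). The adjusted p of the lists not called were 0.0584 for PRC2-bound developmental transcription factors, 0.126 for PRC2-bound signalling genes, 0.387 for naive pluripotency, 0.913 for neuroectoderm, 0.511 for mesoderm, 0.120 for endoderm, 0.699 for trophectoderm, PRC1 and PRC2 subunits and elongation factors, 0.322 for p53 targets, 0.0947 for heat shock, 0.511 for immediate early genes, 0.182 for 2-cell and germline genes, 0.589 for imprinted genes, 0.671 for the cell cycle, 0.180 for glycolysis, 0.142 for cholesterol synthesis, 0.511 for oxidative phosphorylation and 0.685 for interferon genes.

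Both substitutions remove the same lysine, so their mean against EloA_WT was also tested, and the overlap of their calls counted. The mean differed for 239 genes, 21 higher and 218 lower, with 3180 at an unadjusted p under 0.05. Of the 31 genes that fell in EloA_K754M, 22 also fell in EloA_K754R, where 0.865 would be shared if the calls were independent, and no gene rose in both. The shared control libraries raise such overlap by themselves. Without 1 library the 239 became 5 or 10 (EloA_WT replicate 1 or 2), 35 or 13 (EloA_K754M replicate 1 or 2) and 3 or 7 (EloA_K754R replicate 1 or 2), and the balance turned to 23 higher and 12 lower without EloA_K754M replicate 1 and to 8 and 5 without replicate 2. Across 15161 genes the changes of both mutants had a Pearson r of 0.467 and a Spearman rho of 0.502, and groups simulated without any change but with shared controls gave a mean r of 0.502 (0.364 to 0.571 in 100 simulations). The covariance was 0.135, against a simulated mean of 0.0923 (0.0626 to 0.114), so it lay above the simulated range while r lay within its own. The simulated libraries were drawn independently, so a pairing of replicates, if there is one, is not in them. The controls were not split, because each part would keep 1 library, so part of the overlap may come from the sharing. Genes are not independent replicates, so these 3 relations across genes carry no p.

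The mutants were also compared with each other. Usp26 was at 0.149 ± 0.0150 RPKM in EloA_K754M and 2.61 ± 0.433 in EloA_K754R (SD, n = 2 each; adjusted p = 0.0110), and Rab19, a small GTPase gene, at 0.963 ± 0.0733 and 0.248 ± 0.00760 (adjusted p = 0.0408). Tceb3 had a log2 difference of 0.46 (1.46 and 1.98 against 1.12 and 1.30 RPKM; adjusted p = 0.254), Eed of 0.45 (0.334), Ezh2 of −0.05 (0.877), Suz12 of −0.45 (0.199), Pou5f1 of 0.66 (0.334), Nanog of −0.32 (0.309) and Klf4 of −0.24 (0.607). Ribosomal protein genes were higher in EloA_K754M than in EloA_K754R for 34 of 36 (median 0.40; adjusted p = 0.000386, and adjusted p = 0.685 with an estimated correlation), among them Rpl8 (0.87), Rpl13a (0.79), Rpl11 (0.75) and Rps13 (0.74). None was called over all genes, 3 were when adjusted over the list alone, 12 had an unadjusted p under 0.05 and voom called 3. Cholesterol synthesis genes were lower for 21 of 25 (median −0.25; 0.00338, and adjusted p = 0.685 with an estimated correlation), with Scd2 at −0.81, Fdft1 at −0.65, Insig1 at −0.53 and Mvd at 0.46, and glycolysis and hypoxia genes for 19 of 24 (median −0.38; 0.0447, and adjusted p = 0.787 with an estimated correlation), with Ndrg1 at −1.18, Bnip3 at −0.89, Pgk1 at −0.82 and Egln3 at −0.81. In the last 2 lists limma called 0 genes over all genes and over the list alone, 4 and 1 had an unadjusted p under 0.05, and voom called 0. The ribosomal call ended without EloA_K754M replicate 1 (0.0532), the cholesterol call without EloA_K754M replicate 2 (0.168), and the glycolysis call without that library (0.367) or without EloA_K754R replicate 1 (0.966, with the direction turned). With quantile normalization the ribosomal (0.151) and glycolysis calls (0.0979) ended, and with the length trend removed both did (0.0819 each). The glycolysis call also ended with equal medians (0.0638) and from a mean of 0.5 RPKM (0.104). Against EloA_WT the median of the glycolysis list split by replicate number. It was at −0.026 and −0.408 in EloA_K754M replicates 1 and 2, and at 0.483 and −0.356 in EloA_K754R.

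Whether the changes depended on how strongly a gene is transcribed was asked by ranking genes on the pooled CJ7_WT column, which shares no library with the comparison. In the lowest quartile, at a median of 0.147 RPKM, EloA_K754M replicate 2 was higher than EloA_WT by a median log2 of 0.205, while EloA_K754M replicate 1 stood at −0.069 and the EloA_K754R libraries at −0.124 and −0.075. In the highest quartile, at 3.71 RPKM, the 4 libraries stood at −0.031, −0.080, −0.126 and −0.075. Without EloA_K754M replicate 2 the difference between lowest and highest quartile in EloA_K754M was −0.04, and without replicate 1 it was 0.28. The EloA_WT libraries lay 0.039 above and below their mean in the lowest quartile.

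**Figure D2:**
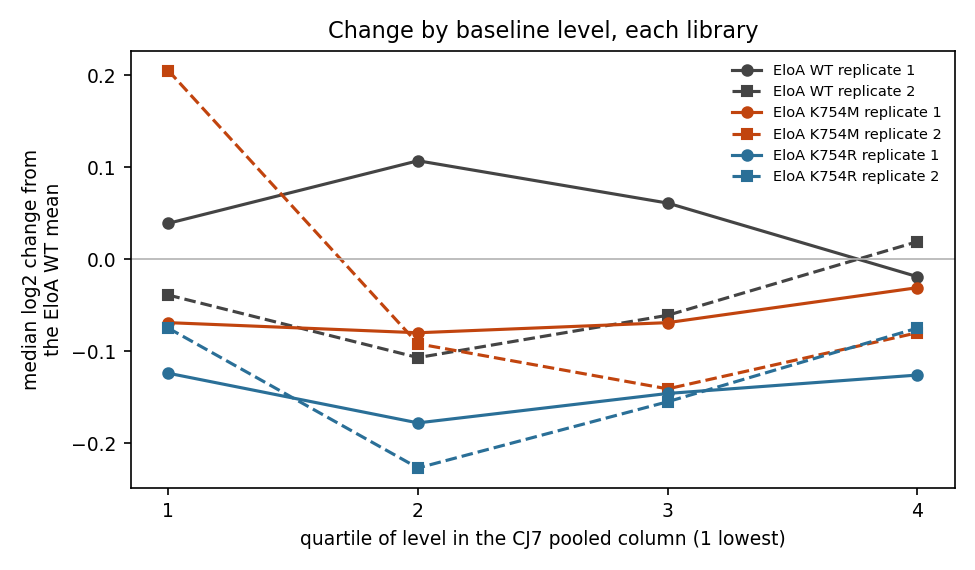
Median log2 change from the EloA_WT mean (vertical axis) of 3790 or 3791 genes in each quartile of pooled CJ7_WT intronic RPKM (horizontal axis, lowest to highest), with 1 line per library. EloA_K754M replicate 2 stands at 0.205 in the lowest quartile, where the other mutant libraries lie between −0.124 and −0.069.

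Change followed the chromosome as well as the gene. The 728 genes of chromosome 11 at 1 RPKM or more had median log2 changes of −0.50 and −0.54 in EloA_K754M and −0.60 and −0.59 in EloA_K754R against EloA_WT, and −0.56 in pooled CJ7_WT and −0.60 in pooled Eed_null. Relative to the other chromosomes these were −0.466 and −0.449, −0.461 and −0.489, and −0.272 in CJ7_WT. In EloA_K754R, chromosome 14 stood at 0.419 and 0.462 and the X chromosome at 0.349 and 0.366 relative to the others. With the library medians made equal within each chromosome, 19 genes were called in EloA_K754M and 95 in EloA_K754R.

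**Figure D3:**
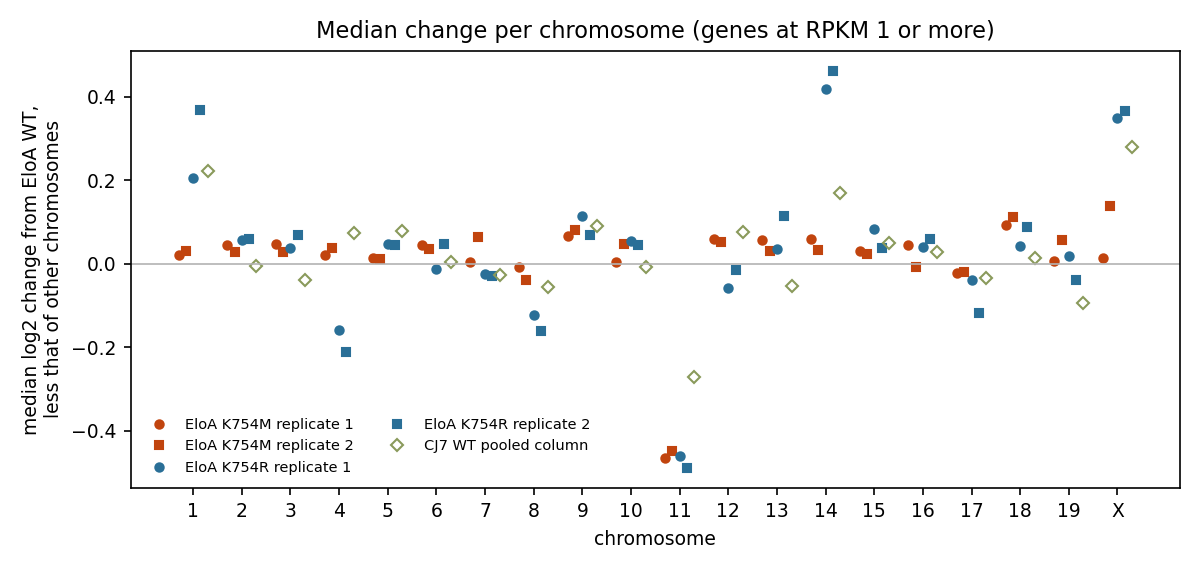
Median log2 change from EloA_WT relative to all other chromosomes (vertical axis) for each chromosome (horizontal axis), in the 4 mutant libraries and the pooled CJ7_WT column. Chromosome 11 lies between −0.489 and −0.449 in the mutants and at −0.272 in CJ7_WT, and chromosome 14 is at 0.419 and 0.462 in EloA_K754R.

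The comparison of Eed_null with CJ7_WT asks what the loss of PRC2 does to transcription. Both exist only as pooled columns, so there is no replicate error and no test, and the intervals given cover counting error only. If the line field is right, the ratios hold a line difference as well, and genes of chromosome 8 and of the X chromosome stood apart as a whole (−0.322 and −0.264 relative to the other chromosomes). Eed stood at 7.97 RPKM in Eed_null and 10.0 in CJ7_WT (1.25-fold lower, 1.23 to 1.28), which does not check the lesion, since its kind is not stated and intronic reads can persist. Developmental transcription factors bound by PRC2 were higher in Eed_null for 30 of 33 genes, 12 of them at least 2-fold (median log2 ratio 0.70, percentile 100.0 among 10000 random lists of like size and level). Prdm16 was 7.41-fold higher (7.07 to 7.77), Pitx1 7.37-fold (4.93 to 11.4), Tbx20 7.86-fold (6.87 to 9.02) and Msx2 5.57-fold (3.49 to 9.27). Hox genes were higher for 22 of 26 (median 0.54, percentile 99.4), with Hoxd10 4.60-fold (1.82 to 13.8), Hoxb2 3.90-fold and Hoxb13 3.00-fold higher (0.866 to 13.1), and Hoxd9 at 4 against 0 reads.

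Endoderm genes had a median log2 ratio of 0.83 (15 genes, percentile 100.0), with Lamb1 3.70-fold, Gata6 3.38-fold (2.94 to 3.91) and Col4a1 2.73-fold higher and Ttr 4.80-fold lower. Mesoderm genes had a median of 0.82 (6 genes, percentile 98.1), with Snai1 5.63-fold, Gata2 3.90-fold, Tbx5 3.79-fold and Kdr 1.86-fold higher. Primed pluripotency genes had a median of 0.48 (16 genes, percentile 99.9), with Lef1 7.45-fold, Lefty1 4.95-fold (3.17 to 7.99), Lefty2 4.39-fold (3.84 to 5.02) and the DNA methyltransferase gene Dnmt3b 3.02-fold higher (2.92 to 3.12). Cholesterol synthesis (0.63, percentile 100.0), ribosomal protein (0.50, 100.0, each of 36 genes positive) and glycolysis genes (0.28, 99.0) lay above the random range as well, with Scd2, Fdps, Insig1 and Dhcr7 3.00-, 2.82-, 2.56- and 2.18-fold, Rpl18, Rps2, Rplp0 and Rps9 1.99-, 1.93-, 1.82- and 1.73-fold, and Egln3, Ndrg1, Bnip3 and Slc16a3 5.61-, 4.65-, 3.07- and 2.15-fold higher. Imprinted genes (median −0.26, percentile 0.0) and very long genes (−0.12, percentile 1.3) lay below it. The random lists were not matched on intron length. Among genes at 1 RPKM or more the median ratio was 0.183 in the shortest eighth by intron length and −0.073 in the longest. The places of lists of long or short genes, the very long genes among them, may therefore hold part of this trend. H19 was 10.0-fold higher on 25 against 3 reads (3.05 to 51.8), Ddc, Rtl1 and Rian were 4.74-, 2.58- and 2.38-fold lower, Auts2 and Gphn were 2.90- and 1.74-fold higher, and Large and Pard3 1.55- and 1.53-fold lower.

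**Figure D4:**
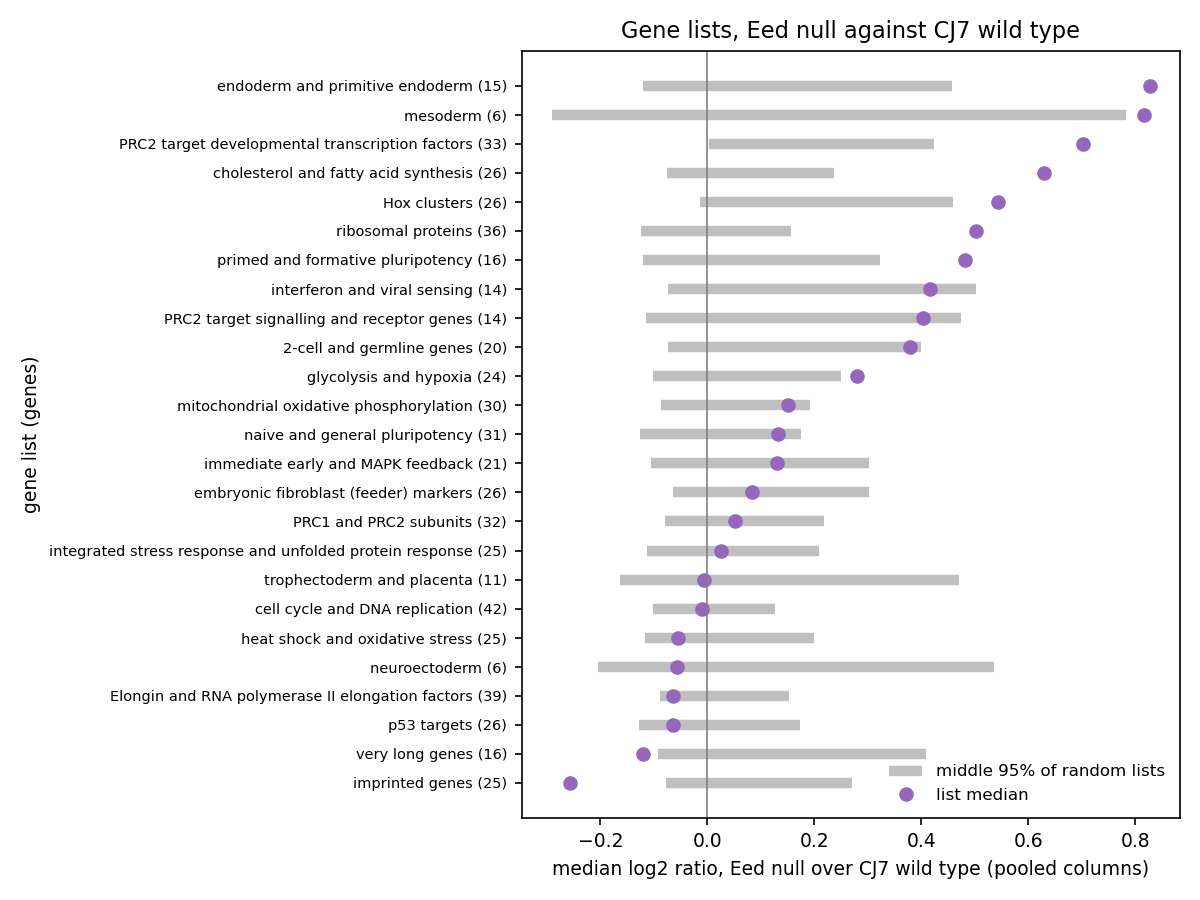
Median log2 ratio of Eed_null to CJ7_WT intronic RPKM (horizontal axis) for each of 25 gene lists (points), over the middle 95% of 10000 random lists of like size and level (grey bars). Endoderm genes (0.83), mesoderm genes (0.82) and PRC2-bound developmental transcription factors (0.70) lie to the right of their bars, and imprinted genes (−0.26) to the left.

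Of 14890 genes, 911 were at least 2-fold higher and 248 at least 2-fold lower in Eed_null. The median ratio of all genes was 0.11, and −0.04 with equal medians, where 644 were higher and 362 lower. The 10 lists named above kept their sign with equal medians and with quantile normalization, but several medians moved. With quantile normalization PRC2-bound developmental transcription factors were at 0.41, Hox genes at 0.25, endoderm and mesoderm genes at 0.54 and 0.52, imprinted genes at −0.42 and very long genes at −0.34, and with equal medians glycolysis genes were at 0.12. The other 15 lists lay within the middle 95% of random lists. These were PRC2-bound signalling genes (0.40, percentile 94.0), 2-cell and germline genes (0.38, 96.5), interferon genes (0.42, 92.3), neuroectoderm (−0.06, 12.1), trophectoderm (−0.01, 16.6), elongation factors (−0.07, 6.4), p53 targets (−0.07, 13.3), heat shock (−0.05, 13.6) and cell cycle genes (−0.01, 36.5), and 6 lists whose sign turned with equal medians, namely naive pluripotency (0.13, 93.2), fibroblast markers (0.08, 35.3), PRC1 and PRC2 subunits (0.05, 43.0), the stress response (0.03, 42.8), immediate early genes (0.13, 65.6) and oxidative phosphorylation (0.15, 92.0).

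The largest single ratios included Sfmbt2, a Polycomb protein gene, at 10.1 against 0.410 RPKM (24.9-fold higher, 24.3 to 25.4), Nod1, a sensor of bacterial peptides, at 3.00 against 0.0998 (30.1-fold, 26.3 to 34.7) and Sema5a, an axon guidance gene, at 1.08 against 0.00716 (151-fold, 135 to 170). Olig2, a neural transcription factor gene, had 51 reads against 0, at least 20.4-fold higher, and Prr18 10 against 0, at least 4.00-fold. Rptn was 13.9-fold higher (7.91 to 26.8), Crx 215-fold on 3 reads in CJ7_WT (73.1 to 1045) and Tmem92 126-fold on 2 reads (34.5 to 1047). Lower in Eed_null were Tmem132d (15.3-fold, 14.6 to 16), Gt(ROSA)26Sor (6.01-fold, 5.37 to 6.74), Myof (5.81-fold, 5.67 to 5.96), Plekhg1 (5.25-fold, 5.12 to 5.38), Ptprv (7.0-fold, 2.77 to 22.7) and Amac1 (8.33-fold on 2 reads, 2.02 to 73.5). Olfr837, Tmem102, Rnf113a2, Calm5 and Npb had at most 3 reads in either column, so no fold is given, and Pspn had 0 reads against 4, at least 1.11-fold lower. Tceb3, Suz12, Pou5f1 and Klf4 were 1.26-, 1.04-, 1.26- and 1.24-fold higher and Ezh2 and Nanog 1.14- and 1.16-fold lower.

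Whether the mutants' changes resemble those of PRC2 loss was asked across genes, with no library shared between both sides. The change in EloA_K754M had a Pearson r of −0.128 and a Spearman rho of −0.119 with the Eed_null ratio, with the same sign for 43% of genes (47.9% if the signs were independent), and the change in EloA_K754R had −0.027 and −0.031, with 45.2% (46.4%). If the line field is right, the mutants' changes set CJ7 against CCE28 and the Eed_null ratio CCE28 against CJ7, so a line difference alone would give negative relations. Sox2 is not analysed here.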

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

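No test in this part was chosen after its result was seen, apart from the counts given by voom and from 50 reads. The groups EloA_K754M and EloA_K754R, each set against the same EloA_WT libraries, differed from one another by limma's test of the difference for 44 genes, 17 higher and 27 lower in EloA_K754M. There were 2806 genes at an unadjusted p under 0.05, and voom called 447. Without 1 library the 44 became 62 (EloA_K754M replicate 1), 11 (EloA_K754M replicate 2), 5 (either EloA_K754R replicate), 18 (EloA_WT replicate 1) or 21 (EloA_WT replicate 2). The balance turned to 53 higher and 9 lower without EloA_K754M replicate 1, to 10 and 1 without replicate 2, and to 232 and 192 from a mean of 50 reads. A replicate block, which stands among the alternatives, turns it too.

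Usp26, an X-linked deubiquitinase gene, had a log2 difference of −3.44 (0.149 ± 0.0150 against 2.61 ± 0.433 RPKM, SD, n = 2 each; adjusted p = 0.0110), with EloA_WT at 0.528 ± 0.160 between the mutants. Ube1y1, a Y-linked ubiquitin-activating enzyme gene, had −3.10 (0.0325 ± 0.0192 against 1.03 ± 0.0501 RPKM on 21 against 850 reads; adjusted p = 0.0294). Rassf10 had −2.98, a value that depends on the offset, since it rests on 0 against 5 reads (adjusted p = 0.0190). Rab19 had 1.61 (0.963 ± 0.0733 against 0.248 ± 0.00760 RPKM; adjusted p = 0.0408) and Masp2, a serine protease gene of the complement system, 1.15 (3.38 ± 0.425 against 1.47 ± 0.0305; adjusted p = 0.0496). Of these 5 genes, none was still called without EloA_K754M replicate 2 or either EloA_K754R replicate, 1 was without EloA_K754M replicate 1, and 2 were without either EloA_WT replicate.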

How the results depend on the processing

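Among the tests in this part, voom, the minimum of 50 recovered reads, equal medians per chromosome, leaving out chromosome 11, removing the length trend and subtracting the receptor background were chosen only after the results were seen, and the cause of a change was not tested except where the setting itself drops genes or samples. Of 1005 values for the 52 gene results past the threshold, 507 stayed past it, 498 kept their direction without passing, and 0 reversed. Of 2269 values for the 117 gene results not past it, 2116 stayed so, 124 passed, and 29 reversed. The 18 list calls kept side and direction in 262 of 338 values, lost the call in 75 and reversed in 1. The stress response list lost its call in both mutants only with an estimated correlation. Depth limits genes with few reads, and the replicates spread far more than counting error (chi-square per degree of freedom 44.5, 38.5 and 32.0 in EloA_WT, EloA_K754M and EloA_K754R).

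Counts are given in the order EloA_K754M against EloA_WT (33), EloA_K754R against EloA_WT (527), mean of both (239) and EloA_K754M against EloA_K754R (44), for those that moved by over 1.5 times. Without a filter they were 16, 160, 50 and 26. With equal medians they were 16, 324, 40 and 68, and with quantile normalization 17, 333, 51 and 90. With voom they were 343, 1332, 899 and 447, and with at least 50 reads, where fewer genes of low precision are tested, 349, 1412, 894 and 424. With equal medians per chromosome the first 3 were 19, 95 and 44, and with the length trend removed 20, 173 and 35. Leaving out chromosome 11 gave 204, 65 and 74 for the last 3. Without a variance trend EloA_K754R gave 228 and the mean 65. With only the 2 groups compared, which leaves fewer samples for the spread, the counts were 3, 1 and, between mutants, 26. Between mutants an offset of 1 gave 27 and a mean of at least 0.5 RPKM 12. Leaving out 1 library gave 2 to 52, 1 to 9, 3 to 35 and 5 to 62.

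As for the lists called (9, 6 and 3), an estimated correlation left 0, 0 and 0 and fry 2, 3 and 0. Quantile normalization left 5 in EloA_K754M and 1 between mutants, where no filter gave 6 and leaving out chromosome 11 gave 5. Leaving out 1 library gave 5 to 8, 6 to 9 and 3 to 6, and the glycolysis list between mutants reversed without EloA_K754R replicate 1 (adjusted p 3.84e-06 to 0.966 over the libraries left out).

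A replicate block raised the counts to 227, 1777, 1046 and 355 genes and gave 10, 7 and 4 lists, with 41 genes higher in EloA_K754M where 2 were without it, and between mutants 154 of the 355 lower where 27 of 44 were. The labels do not establish whether the numbers pair the libraries, but some values split by replicate number in each group. The median of olfactory and vomeronasal receptor genes was 0 RPKM in every replicate 1. It was 0.0281, 0.108 and 0.0374 in replicate 2 of EloA_WT, EloA_K754M and EloA_K754R. Relative to CJ7_WT and to all genes, the glycolysis list was at 1.016, 0.524 and 1.085 in replicates 1 in this order. In replicates 2 it was at −0.114, −0.078 and 0.086. The differences between replicates 1 and 2 correlated across genes between groups with a Pearson r of 0.166, 0.197 and 0.152 (Spearman 0.378, 0.405 and 0.358). EloA_K754M replicate 1 correlated best with EloA_WT replicate 1 (0.935) and every other library with its own group. The fits with a block were not used.

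The difference between lowest and highest quartile was 0.12 in EloA_K754M and 0.38 without a filter, with −0.04 to 0.28 when 1 library was left out. In EloA_K754R it was 0.00, −0.03 and 0.06 with offsets of 0.01 and 1, 0.22 with quartiles of EloA_WT, −0.09 with quantile normalization, 0.17 without a filter, −0.16 from 0.5 RPKM, −0.02 after background subtraction, and −0.05 to 0.10 when 1 library was left out. For Eed_null the genes at least 2-fold apart (911 higher and 248 lower) became 1841 and 133 with offsets of 0.01 and 1 and 537 from 0.5 RPKM. The relation of EloA_K754M to Eed_null was −0.0836 and −0.168 with these offsets, −0.186 from 0.5 RPKM, −0.149 with quantile normalization and −0.132 to −0.0876 when 1 library was left out. That of EloA_K754R was 0.000172, −0.0907 and −0.0947, and −0.0479 to −0.000137. The relation between both mutants was 0.377 to 0.605 when 1 library was left out.

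The reversed genes were all among those not past the threshold. Against EloA_WT in EloA_K754M, Ezh2 became 0.07 with equal medians and 0.04 with quantile normalization. Leaving out 1 library gave Ezh2 −0.17 to 0.05 and Pou5f1 −0.09 to 0.74 (reversed without EloA_K754M replicate 2), Klf4 −0.08 to 0.47 and Tceb3 −0.38 to 0.03 (EloA_K754M replicate 1), and Hoxa2 −0.23 to 2.5 and Hoxd8 −0.24 to 1.64 (EloA_WT replicate 2). In EloA_K754R, equal medians gave Ezh2 0.18 and Eed 0.05, quantile normalization Ezh2 0.16, Eed 0.11, Suz12 0.05 and Pou5f1 0.01, equal medians per chromosome Suz12 0.37, Ezh2 0.09 and Eed 0.04, and removing the length trend Pou5f1 0.01. Leaving out 1 library gave Nanog −0.01 to 0.14 and Neurod1 −0.08 to 0.77 (reversed without EloA_WT replicate 1), Ezh2 −0.09 to 0.07 (0.02 without EloA_WT replicate 1, 0.07 without EloA_K754R replicate 2), Eed −0.39 to 0.10 (0.10 without EloA_WT replicate 2, 0.01 without EloA_K754R replicate 1) and Bmp7 −0.01 to 0.63 (EloA_K754R replicate 1). Between mutants it gave Klf4 −0.51 to 0.04 (EloA_K754M replicate 2), Ezh2 −0.16 to 0.06 (0.06 without EloA_K754M replicate 2, 0.03 without EloA_K754R replicate 1) and Egln3 −1.63 to 0.01 (EloA_K754R replicate 1).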

Other observations

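The tests of chromosome 11 in CJ7_WT, of the stress genes against CJ7_WT and of the lowest quartile in EloA_K754M replicate 1 were chosen only after the results were seen. Genes of the Y chromosome differed between the groups and did not follow the line label. Uty, which encodes a histone demethylase relative, stood at 1.14 and 2.01 RPKM in EloA_WT, 0.309 and 0.406 in EloA_K754M, 1.40 and 1.59 in EloA_K754R, 0.977 in pooled CJ7_WT and 1.34 in pooled Eed_null. The helicase gene Ddx3y stood at 2.33 and 3.98, 0.597 and 0.722, 2.04 and 2.95, 1.06, and 1.73 RPKM, and the translation initiation factor gene Eif2s3y at 3.19 and 4.23, 0.509 and 0.421, 2.75 and 3.13, 0.930, and 2.06.

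Further chromosomes stood apart, some of them in both EloA_K754R and CJ7_WT. In EloA_K754R, genes of chromosome 1 were at 0.205 and 0.367 relative to the other chromosomes, of chromosome 4 at −0.159 and −0.211 and of chromosome 8 at −0.124 and −0.160, and in pooled CJ7_WT genes of the X chromosome at 0.280, of chromosome 14 at 0.168 and of chromosome 1 at 0.221. Between Eed_null and CJ7_WT, genes of chromosome 8 were at −0.322 and of the X chromosome at −0.264. Change also followed intron length. In the shortest eighth of genes, at a median of 0.341 kb, the EloA_K754R libraries were at −0.418 and −0.433 against EloA_WT, and in the longest, at 126 kb, at 0.142 and 0.062. The longest eighth minus the shortest was 0.184 and 0.011 in EloA_K754M, 1.21 in pooled CJ7_WT, and −0.256 between Eed_null and CJ7_WT.

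The first pattern weighed is that genes of chromosome 11 were lower in both mutants than in EloA_WT. The lengths and levels of these genes are argued against as the source, because against other genes of like length and level the weakest of the 4 library shifts was still −0.424, with a spread of 0.096 over the other chromosomes. A different number of chromosome 11 copies in EloA_WT and the mutants is a candidate explanation, since each of 10 consecutive parts of the chromosome was shifted, from −0.566 to −0.415, where a ratio of 2 copies to 3 would give −0.585. The substitution itself stays open: the unsubstituted CJ7_WT column had a matched shift of −0.174, beyond the lowest other autosome at −0.116 by about their spread of 0.062, and unsubstituted Eed_null had −0.278, where chromosome 8 was lower at −0.324, which does not decide it. If the CCE28 label of EloA_WT is right, a difference between parental lines stays open too and was not tested. Eed_null carries that label as well, yet its chromosome 11 genes stood at −0.602 against EloA_WT, and those of CJ7_WT at −0.556. These raw medians include the lower level of other chromosomes in both columns. The matched shifts, −0.278 and −0.174, were smaller than the −0.424 of the weakest mutant library. By either measure Eed_null was shifted at least as far as CJ7_WT. The shift thus did not follow the line label in these pooled columns, though Eed_null also lacks Eed.

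The second pattern is that stress response and serine synthesis genes were lower in both mutants. The chromosome-wide shifts are argued against as the source, since with equal medians per chromosome the list medians were still −0.907 and −0.982. High values in EloA_WT alone may account for part of it, and this was measured against CJ7_WT in 2 ways after the data were seen: for EloA_K754M they differ (weaker library −0.365 relative to genes of like length and level, −0.021 relative to all genes), while in EloA_K754R both lie below CJ7_WT (−0.531 and −0.438), which leaves less room for EloA_WT alone there but does not pass the bound set. The substitution at K754 cannot be told apart from this. Both EloA_WT libraries lay above CJ7_WT, by a matched median of 0.357 and by 0.765 and 0.746 relative to all genes. They also carry another line label than the mutants. Pooled Eed_null carries the line label of EloA_WT and no substitution, yet its list median was −0.796 against EloA_WT. That median is not matched for length, and the shortest eighth of genes in Eed_null was at −0.887 as a whole. Matched for length and level, the list in Eed_null lay at −0.05 against CJ7_WT, and in CJ7_WT at −0.406 against EloA_WT. Eed_null was not matched against EloA_WT directly. On these smaller values too the list did not follow the line label there, though Eed_null differs by the loss of Eed as well. Cell density and the state of the medium, which can also shift these genes, are not given for each sample and were not tested. The inhibitors in the medium are labelled the same for all samples.

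The third pattern is the higher level of weakly transcribed genes in EloA_K754M replicate 2. An even background of reads in that library is a candidate explanation. Olfactory and vomeronasal receptor genes, silent in stem cells, had a median of 0.108 RPKM there. Their median was 0.0281 and 0.0374 in replicate 2 of EloA_WT and EloA_K754R and 0 in every replicate 1. After each library's median was subtracted, the lowest quartile of EloA_K754M replicate 2 stood at −0.265, below the other mutant libraries. The subtraction takes most from this library whatever the source of its reads, so this fall does not decide for a background. Its other quartiles fell as well, to −0.303, −0.234 and −0.119. The methionine substitution as the source is left undecided, since replicate 1, which carries it too, was at −0.069, and 1 library cannot exclude it. The subtraction was chosen after the data were seen, though the bound for its result was set out before that result was known.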
